A study of Mus musculus with 11 samples.

How the data were processed

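Stromal stem and progenitor cells of the marrow were isolated through tdTomato from female mice in which Cre recombinase under the leptin receptor gene switches on this red reporter. Marrow was flushed, digested with enzymes and sorted into lysis buffer, and cDNA was made from poly(A) RNA with the SMART-Seq v4 Plus kit, which does not mark strand. The 11 libraries form 3 groups: 4 from mice given 4 intravenous injections of phosphate-buffered saline (PBS), 3 from mice given 1 injection of doxorubicin at 10 mg/kg (DOX1X), and 4 from mice given 4 injections at 5 mg/kg with 1 week between injections (DOX4X). Cells were collected 8 weeks after treatment. Doxorubicin is an anthracycline that damages DNA by trapping topoisomerase II. The labels number the mice within each group as separate biological replicates.

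The deposited values are whole-number counts per gene, with no normalization, in 1 table of 24718 genes. Per the submitters' processing notes, the tools were FastQC 0.11.5, MultiQC 1.7, Trim Galore 0.6.6, STAR 2.7.9a, SAMtools 1.17 and featureCounts 2.0.1, with the GRCm39 genome build. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with a near-identical copy (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Bglap and its neighbours, the H2 genes and immunoglobulin segments) and genes with an antisense partner (Evx1 and Evx1os) are therefore uncertain as single genes. The genome available here is another build, so no coordinates are given. It was used only to look up symbols, of which 23791 of the 24718 were found.

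One library has labels that disagree. Its title begins with the doxorubicin abbreviation, while its treatment label is PBS and its library name follows the other controls. It was kept as PBS replicate 4. The gene calls, list tests, named genes and the correlation of the comparisons with PBS were also computed without it. The splits, the simulations and the list tests for change in either direction were not. Column names gave the flow cell of each library: PBS 1 to 4 and DOX1X 1 and 2 were on flow cell 1, and DOX1X 3 and DOX4X 1 to 4 on flow cell 2. No PBS library was on flow cell 2 and no DOX4X library on flow cell 1, so DOX4X and PBS can be told apart from the flow cells only through the 3 DOX1X libraries.

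Total counts per library ran from 29540422 to 42784036. Genes were kept by the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 17838 genes holding at least 99.9% of the counts of each library. Libraries were scaled with TMM factors. All 11 libraries were fitted together with group means only, and the 3 differences between groups were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all 17838 genes and a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Levels are CPM scaled by TMM, given as mean ± SD. A set of 30 gene lists (lineages, stress pathways, and markers of other marrow cells that a sort can hold) was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists of a comparison. Of the 726 list genes, 680 were tested.

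The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, leaving out clone names and immunoglobulin and T cell receptor segments; where fewer than 5 genes pass, the 5 with the smallest p instead. It also names up to 4 members with the smallest p of each list described, and 22 key genes whatever their values. For most lists the 2 members with the smallest p are given. Other genes past the threshold that are named were chosen after their values were seen.

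Alternatives were other scaling factors (RLE, upper quartile), no and a stricter low-count filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, a robust dispersion prior, a fit of the compared groups alone, the replicate number as a block, a threshold of 0.10, each library left out, marker genes of other cells left out, and a covariate for blood-cell markers (the mean log2 CPM of the neutrophil, monocyte and macrophage, B lineage and erythroid lists, prior count 2, centred). Lists were also tested with an estimated correlation and with fry. Flow cell as a covariate, fits within a flow cell and an estimated correlation together with a covariate were added after seeing the data. The procedure was tested on simulated data with the real means, library sizes and dispersions. For DOX4X against PBS, edgeR recovered 32.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 95.5% of those changed 4-fold among 17507 genes, with 10 false calls of 146, and DESeq2 gave 49 false calls of 206. For DOX1X against PBS the shares recovered by edgeR were 14.9%, 67.2% and 93.9%.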

Results

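Bulk RNA-seq was done on tdTomato-sorted marrow stromal cells (mesenchymal stem and progenitor cells traced by the leptin receptor) from 11 female mice, 8 weeks after PBS (4 mice), a single dose of doxorubicin (DOX1X, 3 mice) or 4 weekly doses (DOX4X, 4 mice). The design asks what doxorubicin chemotherapy leaves behind in these skeletal progenitors. Total counts per library ran from 29540422 to 42784036 in PBS, from 33496356 to 42002065 in DOX1X and from 31129352 to 36888310 in DOX4X. Cxcl12, the chemokine that marks these niche cells, stood at 53730 CPM ± 3101 (SD, n = 4) in PBS, 53383 ± 5928 (n = 3) in DOX1X and 50085 ± 5131 (n = 4) in DOX4X.

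After 4 doses, 26 of 17838 genes differed from PBS and all 26 were lower (edgeR's quasi-likelihood test, adjusted p under 0.05). The rule for named genes gives 10 of them. Spp1 (osteopontin, a secreted bone matrix protein) fell by 1.58 on the log2 scale (SE 0.21, edgeR adjusted p = 0.037), from 7971 CPM ± 1736 (SD, n = 4) to 2662 ± 713 (n = 4). Mmp13 (a collagenase of bone and cartilage) fell by 1.27 (SE 0.18), from 3770 CPM ± 488 to 1561 ± 330. Mmp9 (a gelatinase) fell by 1.92 (SE 0.27), from 75.5 CPM ± 33.1 to 20.01 ± 2.31. Timp1 (an inhibitor of metalloproteinases) fell by 1.18 (SE 0.13), and its edgeR adjusted p of 0.017 was the smallest of the comparison. Fam20c (the kinase of secreted phosphoproteins) fell by 1.41 (SE 0.23), Bmp8a (a bone morphogenetic protein) fell by 1.40 (SE 0.21), and Paqr5 (a membrane progestin receptor) fell by 1.19 (SE 0.18). Slit2 (a secreted guidance ligand) fell by 1.05 (SE 0.18), P4ha3 (a collagen prolyl hydroxylase subunit) fell by 1.03 (SE 0.15) and Itgb5 (an integrin subunit) fell by 1.00 (SE 0.15). The other 16 genes lay outside the rule for named genes, and those named here were chosen after their values were seen. Evx1os fell by 2.61, Chst8 fell by 2.53, Evx1 fell by 2.24 and St6gal2 fell by 1.62, all at low levels. Evx1 and Evx1os are antisense partners whose reads cannot be told apart without strand. Tmem100 fell by 0.96, Sdc3 fell by 0.83, Qsox1 fell by 0.78, Serpine2 fell by 0.70, Enpp3 fell by 0.62 and Robo1 (a Slit receptor) fell by 0.61. Ddr2 (a collagen receptor) fell by 0.59, Tmem123 fell by 0.57, Epb41l3 fell by 0.57, Gpr27 fell by 0.56, Ctsb (a cathepsin) fell by 0.48 and Skil fell by 0.45. For each of the 26 genes, which were chosen by their p, the 4 DOX4X libraries lay below the 4 PBS libraries. Over all 17838 genes these groups did not overlap for 834 lower and 566 higher genes (7.85%, against 2.86% by chance). No gene rose past the threshold with edgeR, although 1071 genes were higher at an unadjusted p under 0.05. DESeq2 called 178 higher and 412 lower genes, and limma-voom with quality weights called 4 higher and 52 lower.

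The number of calls changed with single libraries and with the flow cell. The edgeR adjusted p of the 26 genes lay between 0.017 (Timp1) and 0.048 (Fam20c and Slit2), so small shifts can move many past the threshold. With a library left out, their median log2 fold change lay between -1.11 and -0.88, though they were chosen for their fall. The number of calls was 3 without PBS 1, 3 without PBS 2, 3 without PBS 3, and 80 without PBS 4 (the library whose labels disagree). It was 1 without DOX1X 1, 3 without DOX1X 2, and 47 without DOX1X 3. It was 0 without DOX4X 1, DOX4X 2 or DOX4X 3 (1914, 1725 and 2352 genes at an unadjusted p under 0.05) and 7 without DOX4X 4. It was 1 (Timp1) with only the compared groups in the fit and 5 with the blood-cell marker covariate. All PBS libraries were on flow cell 1 and all DOX4X libraries on flow cell 2. For DOX4X against PBS, flow cell as a term therefore joins DOX1X 1 and 2 against PBS with DOX4X against DOX1X 3 alone. Values of this comparison with the term, here and below, rest in part on that single library. With flow cell as a term, none of the 26 genes passed the threshold and 24 had an unadjusted p under 0.05. The median of their log2 fold changes was -0.97 (median SE 0.29) in place of -1.02 (median SE 0.15). The fold change was smaller by over 1.5 times for Mmp9 (-1.16), P4ha3 (-0.68) and Serpine2 (-0.44).

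**Figure D1:**
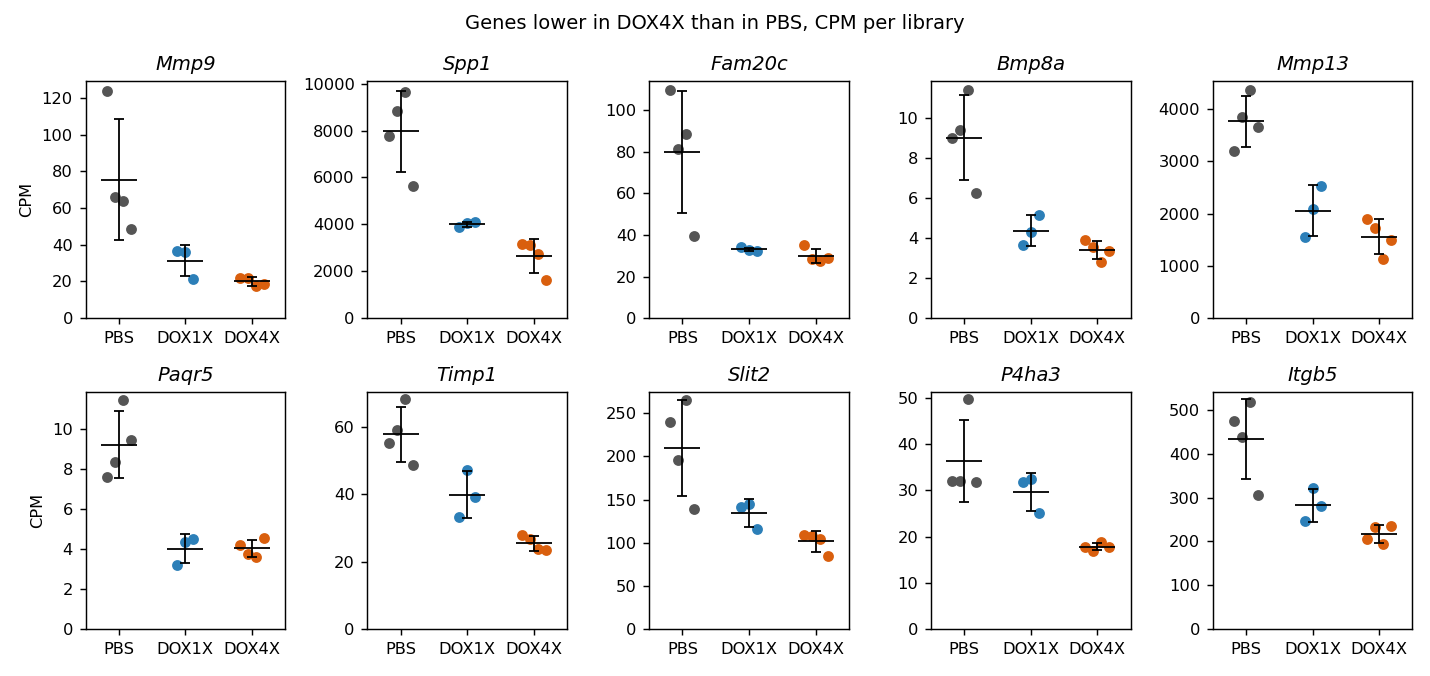
CPM (linear axis from 0) of the 10 named genes lower in DOX4X than in PBS, with 1 point per library (PBS n = 4, DOX1X n = 3, DOX4X n = 4), horizontal bars at group means and whiskers of 1 SD. In each panel the DOX4X points lie below the PBS points; for Spp1 the means are 7971 in PBS, 4007 in DOX1X and 2662 in DOX4X.

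Lists of bone and matrix genes lay lower after 4 doses. Of 30 lists, 14 passed the camera threshold at the preset correlation (10 higher, 4 lower), and 0 did with an estimated correlation (4 at an unadjusted p under 0.05, and 1 past the threshold with fry). Of 26 measured genes of the osteoblast lineage and bone matrix, 24 were lower (median log2 fold change -0.42, camera adjusted p = 1.21e-10, and adjusted p = 0.27 with an estimated correlation). Of these, 2 fell when adjusted over all genes tested (Spp1 and Mmp13) and 7 when adjusted over the list alone. Dmp1, an osteocyte matrix protein, had a log2 fold change of -2.00 (SE 0.44, edgeR adjusted p = 0.11), and Ibsp, bone sialoprotein, -0.63 (SE 0.15, edgeR adjusted p = 0.12). With flow cell as a term Ibsp had -0.20 (edgeR adjusted p = 0.86), while Dmp1 lay between -2.41 and -1.78 in all its alternatives. Of 41 extracellular matrix and fibrosis genes, 35 were lower (median -0.40, camera adjusted p = 1.09e-17, and adjusted p = 0.26 with an estimated correlation), 1 (Timp1) over all genes tested and 14 when adjusted over the list alone. Loxl1 (a lysyl oxidase, -0.73, SE 0.14), Fbn1 (fibrillin 1, -0.65, SE 0.13) and Col6a2 (a type VI collagen chain, -0.65, SE 0.13) did not pass over all genes, with edgeR adjusted p of 0.083, 0.10 and 0.10. The senescence and secretory phenotype list was also lower (20 of 31 genes, median -0.06, camera adjusted p = 5.91e-05, and adjusted p = 0.13 with an estimated correlation). Its 5 called members, Timp1, Spp1, Mmp9, Mmp13 and Serpine2, encode matrix proteins, proteases and protease inhibitors, and 6 fell when adjusted over the list alone. Spp1 and Mmp13 are also the called genes of the osteoblast list, and Timp1 that of the matrix list. The 3 lists are therefore not separate results, and they were not tested without the shared genes. The senescence list was the 1 list past the threshold with fry (adjusted p = 0.048). Sterol synthesis and uptake genes were lower in 17 of 22 (median -0.20, camera adjusted p = 0.021, and adjusted p = 0.63 with an estimated correlation), with none called over the list alone. Hmgcs1 had -0.32 (SE 0.14) and Acat2 -0.19 (SE 0.10). The sterol call was lost without PBS 1, PBS 2, DOX4X 1 or DOX4X 2 (camera adjusted p = 0.066, 0.45, 0.087 and 0.18), with the blood-cell marker covariate (0.25) and with flow cell as a term (0.68). With flow cell as a term the osteoblast median was -0.15 (camera adjusted p = 0.016), the matrix median -0.21 (0.0026) and the senescence median -0.17 (0.019), with adjusted p of 0.83, 0.83 and 0.47 with an estimated correlation. The osteoblast median was -0.27 without PBS 1, and the senescence median -0.10 without PBS 1, -0.13 without PBS 3 and -0.13 without DOX4X 1.

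The other lists past the camera threshold lay higher after 4 doses. Of 26 adipocyte and lipid storage genes, 16 were higher (median 0.22, camera adjusted p = 0.0019, and adjusted p = 0.47 with an estimated correlation), 0 over all genes tested with edgeR (7 higher at an unadjusted p under 0.05) and 3 when adjusted over the list alone. Fabp4 (a fatty acid binding protein, 1.42, SE 0.35) and Cd36 (a fatty acid transporter, 1.37, SE 0.38) are also expressed by endothelium. Pparg (the master regulator of adipogenesis) had 0.47 (SE 0.14), Lpl (lipoprotein lipase) 0.47 (SE 0.15), and the 4 edgeR adjusted p lay at 0.13, 0.17, 0.18 and 0.22. With flow cell as a term Fabp4 had 0.33 (edgeR adjusted p = 0.90), Pparg 0.64 (0.51) and Lpl 1.05 (0.26). The list still passed with this term (median 0.30, camera adjusted p = 0.016, and adjusted p = 0.82 with an estimated correlation). Without PBS 4 the list no longer passed (camera adjusted p = 0.069), and its median was 0.36 without PBS 1 and 0.13 without PBS 3. All 38 cell-cycle genes were higher (median 0.73, camera adjusted p = 9.09e-12, and adjusted p = 0.58 with an estimated correlation), with 0 called by edgeR over all genes or over the list alone and 5 higher at an unadjusted p under 0.05. Cenpa had 0.83 (SE 0.30) and Cdk1 0.79 (SE 0.29). The cell-cycle median was 1.90 with flow cell as a term (camera adjusted p = 4.61e-30, and adjusted p = 0.47 with an estimated correlation), -0.06 with the blood-cell marker covariate (0.76) and 0.48 without DOX4X 1. DNA repair genes were higher in 24 of 32 (median 0.13, camera adjusted p = 0.0093, and adjusted p = 0.60 with an estimated correlation), with Chek2 at 0.60 (SE 0.16) and Xrcc6 at 0.34 (SE 0.11). The DNA repair call was lost without PBS 4 or DOX4X 1 (camera adjusted p = 0.11 for both) and with the marker covariate (0.98), and its median was 0.33 with flow cell as a term. Nuclear-encoded oxidative phosphorylation genes were higher in 31 of 39 (median 0.07, camera adjusted p = 0.013, and adjusted p = 0.60 with an estimated correlation), with Cox5b at 0.23 (SE 0.06) and Cox8a at 0.18 (SE 0.07). That call was lost without PBS 1, PBS 3 or DOX4X 3 (camera adjusted p = 0.068, 0.073 and 0.17) and with flow cell as a term (0.27). All 11 mitochondrially encoded transcripts were higher (median 0.17, camera adjusted p = 0.013, and adjusted p = 0.60 with an estimated correlation), with mt-Nd6 at 0.32 (SE 0.11) and mt-Nd2 at 0.26 (SE 0.14). Their call was lost without PBS 2 or DOX4X 3 (camera adjusted p = 0.18 and 0.27), and their median was -0.0086 with flow cell as a term and 0.27 without PBS 4.

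Markers of other marrow cells moved with these groups. The blood-cell marker score was -0.49 ± 0.41 (SD, n = 4) in PBS, 0.39 ± 0.63 (n = 3) in DOX1X and 0.20 ± 0.48 (n = 4) in DOX4X, in log2 units around the mean of all libraries. In DOX4X against PBS, 20 of 21 B lineage markers were higher (median 1.11, camera adjusted p = 4.27e-11, and adjusted p = 0.33 with an estimated correlation), 13 when adjusted over the list alone, among them Cd79a (1.27, SE 0.35) and Vpreb3 (1.42, SE 0.42). All 15 erythroid markers were higher (median 1.05, camera adjusted p = 1.13e-10, and adjusted p = 0.33 with an estimated correlation), 8 over the list alone, with Hbb-bt at 1.49 (SE 0.39) and Hba-a2 at 1.08 (SE 0.33). All 19 T and natural killer cell markers (median 1.07, camera adjusted p = 9.35e-07, and adjusted p = 0.26 with an estimated correlation) and all 22 endothelial markers (median 0.85, camera adjusted p = 4.48e-12, and adjusted p = 0.34 with an estimated correlation) were higher, with 1 of each called over the list alone. Ccl5 had 1.53 (SE 0.35), Trbc2 1.51 (SE 0.53) and the endothelial gene Eng 0.40 (SE 0.13). With flow cell as a term the endothelial list no longer passed (median 0.04, camera adjusted p = 0.65), and the medians were 2.68 for erythroid, 2.20 for T and natural killer cell, 1.77 for B lineage and 0.74 for monocyte markers. These medians rest in part on DOX1X 3, the only DOX1X library on flow cell 2. Its blood-cell marker score was -0.31, against 0.89 in DOX1X 1 and 0.60 in DOX1X 2. Monocyte and macrophage markers were higher in 14 of 19 (median 0.42, camera adjusted p = 0.030, and adjusted p = 0.61 with an estimated correlation), while Cd163 had -0.70 (SE 0.26) and Mrc1 1.06 (SE 0.42). This call was lost without PBS 1, PBS 2, PBS 4, DOX4X 1 or DOX4X 2 (camera adjusted p = 0.12, 0.064, 0.20, 0.27 and 0.088), and the median was 0.79 without PBS 3. With the blood-cell marker covariate the monocyte list (median -0.38, camera adjusted p = 0.067), the cell-cycle list (0.76) and the T and natural killer cell list (0.093) did not pass, and the osteoblast and matrix lists did (medians -0.51 and -0.53, adjusted p = 0.32 for both with an estimated correlation). The erythroid and B lineage medians were 0.28 and 0.66 with it. The covariate was built from the erythroid, B lineage, monocyte and neutrophil lists, so lower values of these lists with it follow from its construction.

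**Figure D2:**
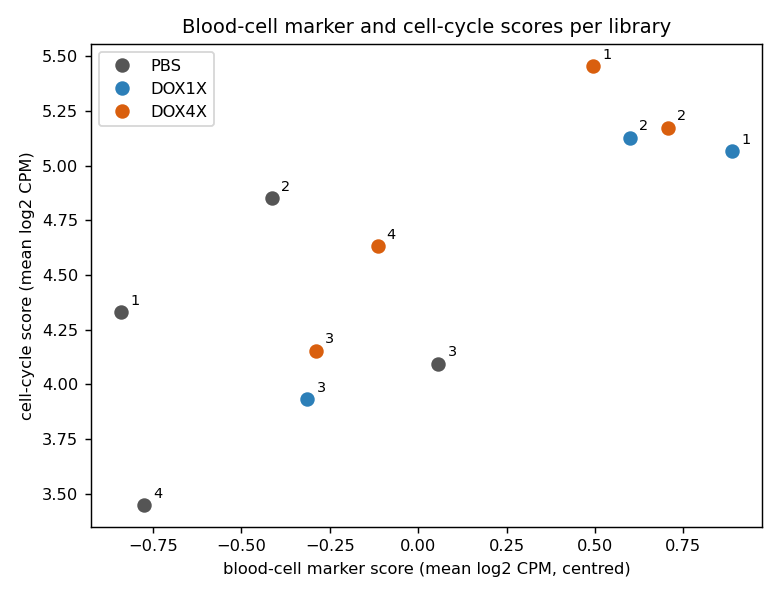
Blood-cell marker score (horizontal axis, mean log2 CPM centred on all libraries) against cell-cycle score (vertical axis, mean log2 CPM of 38 genes), with 1 point per library coloured by group and numbered by replicate. PBS libraries average -0.49, DOX1X 0.39 and DOX4X 0.20 on the horizontal axis.

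**Figure D3:**
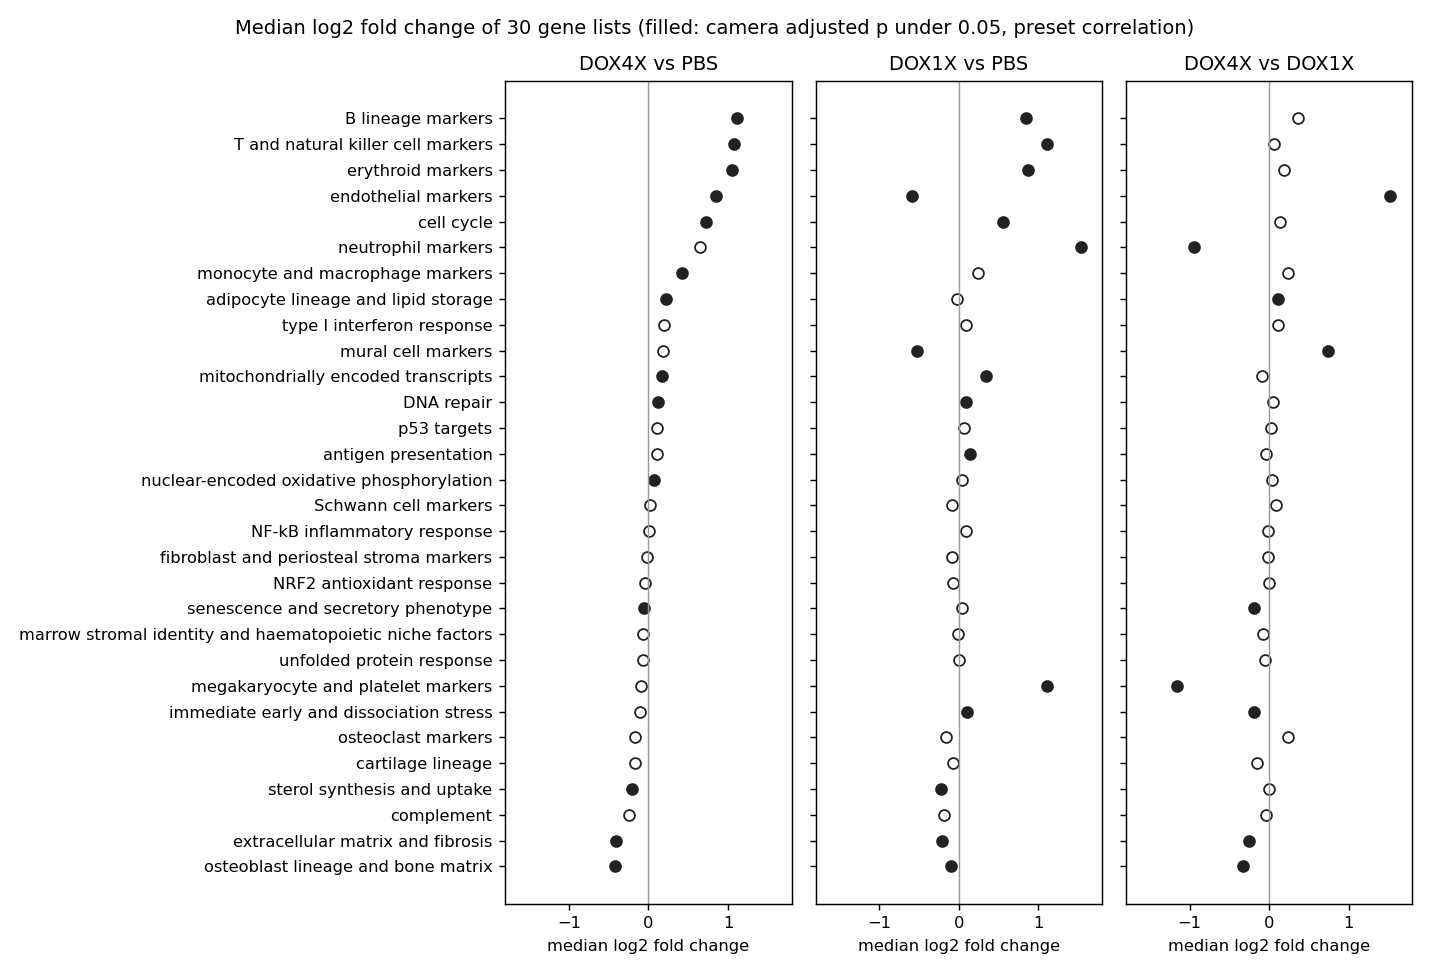
Median log2 fold change (horizontal axis) of each of 30 gene lists in the 3 comparisons, ordered by DOX4X against PBS; filled points passed the camera threshold at the preset correlation and open points did not. The osteoblast and matrix lists lie lowest in DOX4X against PBS (-0.42 and -0.40), and endothelial markers lie at 0.85, -0.58 and 1.51 in the 3 panels.

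Among the key genes of the haematopoietic niche, of osteogenic differentiation and of the p53 response, Spp1 (above) passed the threshold after 4 doses and the others tested did not. The list of marrow stromal identity and niche factors had a median of -0.06 over 23 genes (camera adjusted p = 0.22), with 1 higher and 2 lower when adjusted over the list alone. Log2 fold changes were -0.10 (SE 0.11) for Cxcl12, 0.05 (SE 0.10) for Kitl (stem cell factor), 0.02 (SE 0.12) for Csf1, -0.06 (SE 0.11) for Angpt1, -0.18 (SE 0.15) for Il7, 0.23 (SE 0.13) for Vcam1 and -0.36 (SE 0.16) for Lepr, whose edgeR adjusted p was 0.36. In the osteogenic lineage, Runx2 had -0.26 (SE 0.07, edgeR adjusted p = 0.16), Sp7 -0.24 (SE 0.13), Alpl -0.40 (SE 0.24), Col1a1 -0.69 (SE 0.53) and Bglap 0.10 (SE 0.34), and Adipoq had 0.17 (SE 0.12). The p53 targets had a median of 0.11 over 32 genes (camera adjusted p = 0.25), with Cdkn1a at -0.02 (SE 0.24) and Mdm2 at 0.03 (SE 0.08). Il6 had 0.10 (SE 0.27), Ccl2 0.33 (SE 0.25) and Mki67 0.76 (SE 0.42, edgeR adjusted p = 0.46, and 2.20 with flow cell as a term, adjusted p = 0.42). Cdkn2a, the senescence marker, lay at or under 0.163 CPM in each library and was not tested. The remaining lists did not pass: type I interferon response (median 0.20, camera adjusted p = 0.067), NF-kB inflammatory response (0.00, 0.35), antigen presentation (0.10, 0.063), and complement (-0.24, 0.063), each as the median and its camera adjusted p. In the same terms, the others were unfolded protein response (-0.06, 0.25), cartilage lineage (-0.17, 0.29), immediate early and dissociation stress (-0.11, 0.063), neutrophil (0.64, 0.34), mural (0.18, 0.34), megakaryocyte and platelet (-0.10, 0.89), Schwann cell (0.01, 0.37) and osteoclast markers (-0.17, 0.19). For Schwann cell markers the mean was -0.29 and the camera direction downward.

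After a single dose, 1 gene passed the threshold against PBS. The PBS mice had 4 injections and the DOX1X mice 1, so this comparison also differs in the number of injections. Ighv5-17, an immunoglobulin heavy chain variable segment, rose by 6.53 on the log2 scale (SE 0.45, edgeR adjusted p = 1.29e-04), with 12.7, 14.0 and 5.81 CPM in the 3 DOX1X libraries against 0.112 CPM on average in PBS and 0.283 in DOX4X. All 21 B lineage markers were also higher in DOX1X (below), and whether its RNA came from such cells was not tested. The next genes by p were Paqr5 (-1.20, SE 0.20), Xcl1 (2.37, SE 0.43), Chst8 (-2.25, SE 0.42) and Evx1 (-2.21, SE 0.41), none past the threshold (edgeR adjusted p = 0.44 for each). Spp1 had -0.99 (SE 0.23), Mmp13 -0.87 (SE 0.20), Mmp9 -1.27 (SE 0.29) and Timp1 -0.54 (SE 0.14), each with an edgeR adjusted p of 0.52. At an unadjusted p under 0.05, 1278 genes differed (891.9 expected by chance); DESeq2 called 49 genes and limma-voom 1. Within flow cell 1 (DOX1X 1 and 2 against the 4 PBS libraries) 5 genes passed, Ighv5-17, Ighv11-2, Igkv14-126, Mical2 and Mmd2, the last 4 chosen after their values were seen, and Spp1 had -1.01 (SE 0.21) there. The count was 2 without PBS 4, DOX1X 1, DOX1X 2 or DOX4X 4.

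Of the 30 lists, 15 passed the camera threshold after a single dose (10 higher, 5 lower), and 0 with an estimated correlation (2 at an unadjusted p under 0.05) or with fry; with the blood-cell marker covariate 7 passed. Extracellular matrix genes were lower in 33 of 41 (median -0.22, camera adjusted p = 7.17e-06, and adjusted p = 0.66 with an estimated correlation), with Ccn2 at -0.83 (SE 0.19) and 2 called over the list alone. Osteoblast genes were lower in 20 of 26 (median -0.09, camera adjusted p = 0.024, and adjusted p = 0.69 with an estimated correlation), with Mmp13 and Spp1 as above and 2 called over the list alone. This call was lost without PBS 1, PBS 2, PBS 3, DOX1X 2 or DOX1X 3 (camera adjusted p = 0.42, 0.30, 0.068, 0.065 and 0.25) and within flow cell 1 (0.15). Leaving out DOX1X 3 and staying within flow cell 1 both compare DOX1X 1 and 2 with the PBS libraries. Here and below they are therefore not separate results, and the flow cell cannot be told apart from DOX1X 3. Sterol genes were lower in 18 of 22 (median -0.22, camera adjusted p = 0.014, and adjusted p = 0.69 with an estimated correlation), with Nsdhl at -0.29 (SE 0.14) and Stard4 at 0.31 (SE 0.15). The sterol call was lost without PBS 1, PBS 2, DOX1X 2 or DOX1X 3 (camera adjusted p = 0.053, 0.47, 0.20 and 0.13) and within flow cell 1 (0.11). Of the neutrophil markers 19 of 20 were higher (median 1.53, camera adjusted p = 3.31e-08, and adjusted p = 0.64 with an estimated correlation), with Lcn2 at 1.72 (SE 0.45), while Mmp9, also on this list, had -1.27. All 21 B lineage (median 0.84, Dntt 1.61, SE 0.49), 15 erythroid (0.87, Hbb-bt 1.37, SE 0.41), and 19 T and natural killer cell markers (1.10, Lck 1.13, SE 0.38) were higher, with adjusted p of 0.64, 0.64 and 0.60 with an estimated correlation. So were 15 megakaryocyte and platelet (1.10, Vwf 1.29, SE 0.66), 38 cell-cycle (0.56, Cdk1 0.76, SE 0.31) and 11 mitochondrially encoded genes (0.34, mt-Nd4 0.41, SE 0.14), with an adjusted p of 0.66 for each with an estimated correlation. Without DOX1X 2, Vwf had -0.019 and Tubb1 -0.20, against 1.82 (SE 0.98) for Tubb1 with it, and the megakaryocyte call was lost (median -0.18, camera adjusted p = 0.63). DNA repair (22 of 32 higher, median 0.10, Polq 0.96, SE 0.31), antigen presentation (17 of 22, 0.14, H2-Eb1 0.81, SE 0.25) and immediate early genes (24 of 32, 0.10, Ier5 0.57, SE 0.17, and Nr4a1 -0.43, SE 0.16) were higher, with adjusted p of 0.69, 0.66 and 0.70 with an estimated correlation. Endothelial (21 of 22, -0.58, Cdh5 -0.80, SE 0.45, and Vwf 1.29) and mural markers (15 of 17, -0.53, Des -0.39, SE 0.13) were lower, with adjusted p of 0.69 and 0.66 with an estimated correlation. Of these, the DNA repair call was lost without PBS 3, PBS 4, DOX1X 1 or DOX1X 2 (camera adjusted p = 0.062, 0.27, 0.17 and 0.38) and antigen presentation without PBS 4, DOX1X 2 or DOX1X 3 (0.092, 0.065 and 0.12) and within flow cell 1 (0.15). Immediate early genes lost it without PBS 1, PBS 2, PBS 3 or DOX1X 3 (camera adjusted p = 0.42, 0.39, 0.070 and 0.74) and within flow cell 1 (0.88), endothelial markers without PBS 1, PBS 2 or DOX1X 1 (0.17, 0.37 and 0.33) and mural markers without PBS 1 (0.28). Other medians moved by over 1.5 times with a library left out. Without DOX1X 1 they were -0.17 for osteoblast, 0.35 for cell-cycle, 0.32 for antigen presentation, 0.91 for neutrophil, 0.62 for T and natural killer and -0.34 for mural genes. Without DOX1X 3 they were -0.11 for matrix, 0.84 for cell-cycle, 0.15 for DNA repair, -0.94 for endothelial and -0.81 for mural genes. Without PBS 4 they were -0.25 for osteoblast, 0.36 for cell-cycle, 0.21 for immediate early and -0.90 for endothelial genes. The cell-cycle median was 0.88 without PBS 2, 0.33 without DOX1X 2 and 0.84 within flow cell 1. The antigen presentation median was 0.24 without PBS 2 and the megakaryocyte median 1.95 without PBS 1. With the blood-cell marker covariate, built from neutrophil, monocyte and macrophage, B lineage and erythroid markers, cell-cycle genes were lower (median -0.38, camera adjusted p = 0.0092, and adjusted p = 0.86 with an estimated correlation). With it DNA repair (median -0.16, camera adjusted p = 0.30), mural (0.094, 0.57), sterol (-0.071, 0.57) and immediate early genes (0.089, 0.11) did not pass. Nor did erythroid (median -0.089, camera adjusted p = 0.75), neutrophil (0.41, 0.30), B lineage (0.21, 0.14), T and natural killer (0.16, 0.62), endothelial (-0.35, 0.17) and megakaryocyte markers (0.68, 0.30).

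Between the dosing schedules, Ighv5-17 was the 1 gene past the threshold, lower in DOX4X than in DOX1X (log2 fold change -5.24, SE 0.40, edgeR adjusted p = 4.93e-04). At an unadjusted p under 0.05, 778 genes differed (891.9 expected by chance); DESeq2 called 27 genes, 20 of them higher in DOX4X, and limma-voom 1. Without DOX1X 1 the count was 2. The next genes by p, Otogl (3.94, SE 0.67), Sntg2 (1.73, SE 0.33), Gm21698 (-4.18, SE 0.80) and Arap3 (1.16, SE 0.23), did not pass (edgeR adjusted p of 0.73 for Otogl and 0.89 for the others). Of the 30 lists, 9 passed the camera threshold (3 higher, 6 lower), and 0 with an estimated correlation (2 at an unadjusted p under 0.05) or with fry. Endothelial markers were higher in DOX4X in 21 of 22 genes (median 1.51, camera adjusted p = 6.44e-37, and adjusted p = 0.14 with an estimated correlation), 20 when adjusted over the list alone, with Fabp4 at 1.53 (SE 0.38) and Eng at 0.53 (SE 0.14). Adipocyte genes (20 of 26, median 0.11, Cd36 1.51, SE 0.42) and mural markers (15 of 17, 0.74, Kcnj8 1.18, SE 0.36) were higher, with an adjusted p of 0.41 for both with an estimated correlation. Lower in DOX4X were osteoblast (21 of 26, median -0.33, Ibsp -0.56, SE 0.16), extracellular matrix (34 of 41, -0.26, Col12a1 -0.57, SE 0.14), and senescence genes (22 of 31, -0.19, Timp1 -0.65, SE 0.13), with adjusted p of 0.41, 0.41 and 0.067 with an estimated correlation. Also lower were immediate early (26 of 32, -0.19, Socs3 -0.64, SE 0.17), neutrophil (16 of 20, -0.94, Il1r2 -1.65, SE 0.47) and megakaryocyte genes (15 of 15, -1.15, Tubb1 -2.60, SE 1.01), with adjusted p of 0.41, 0.41 and 0.58 with an estimated correlation. Within flow cell 2 the DOX1X arm was 1 mouse (DOX1X 3, assumed to vary like the 4 DOX4X libraries), and the values there rest on it. Ighv5-17 had -4.33 there and did not pass. In its other alternatives the adjusted p lay between 2.03e-31 (DESeq2) and 0.0081 (limma-voom). Ighg1, chosen after its value within flow cell 2 was seen, stood at 124, 0 and 144 CPM in the 3 DOX1X libraries and at 0 in each DOX4X library. The neutrophil median was 0.37 there, the megakaryocyte median 0.18, the adipocyte median 0.33, the osteoblast median -0.083, the immediate early median -0.35 and the endothelial median 0.92. The neutrophil, megakaryocyte, matrix (median -0.10) and mural lists (median 0.26) did not pass there. Without DOX1X 2 the megakaryocyte median was 0.07 (camera adjusted p = 0.59), the matrix median -0.15 and the senescence median -0.12. The adipocyte median was 0.17 and the neutrophil median -0.54 without DOX1X 1, and the senescence median was -0.29 and the immediate early median -0.11 without DOX1X 3.

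The 2 comparisons with PBS shared their controls. All 26 genes lower after 4 doses were also lower after a single dose (median log2 fold change -0.58), 22 of them at an unadjusted p under 0.05. Within flow cell 1 the counts were 26 and 22 (median -0.55). In simulated unchanged groups with shared controls, 92.9% of as many top genes had the same sign on average (76.9% to 100%), a range that holds the observed share. With a limma fit on log2 CPM, 21 of the top 26 genes had the same sign and an unadjusted p under 0.05 after a single dose, against 12.7 in the simulations (7 to 19). The correlation of log2 fold changes across the 17838 genes, which are not independent replicates, was 0.60, against 0.47 in 100 simulations of unchanged groups (0.43 to 0.50). It had a mean of 0.17 with the PBS libraries split between the comparisons (-0.01 to 0.23), where no simulated range is available. The covariance was 0.108 against a simulated 0.0597, a difference of 0.0479. At an unadjusted p under 0.05, with a limma fit on log2 CPM, 328 genes were higher and 418 lower in both, against 100.2 and 74.7 in the simulations, and 39.6 and 54.2 for independent lists. The simulations took means, library sizes and dispersions from the data, but not the correlation between genes. From the fit of all 11 libraries, this correlation was estimated at 0.92 for the cell-cycle list in DOX4X against PBS. The simulated ranges may therefore be too narrow, and values outside them cannot show a shared effect of doxorubicin. Markers of other marrow cells higher in both groups, and the flow cell that a single-dose library shared with the 4-dose group, were not simulated.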

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

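The tests of flow cell, stromal share, the label of PBS 4 and splits with the 8 libraries fitted alone were chosen only after the results they address had been seen. In 238 groups of 4 libraries, 12 held a library farther from the rest than Dixon's 95% limit allows, and chance alone gives about 1 in 20 groups (11.9). In DOX4X 3, Ccl5 stood at 1.02 CPM (others 2.72 to 3.06), Des at 33.6 (23.6 to 24.8) and Enpp3 at 98.7 (116 to 119). In DOX4X 4, Col6a2 stood at 974 CPM (others 662 to 697), Fbn1 at 1127 (853 to 869), Dntt at 4.69 (2.89 to 3.16) and St6gal2 at 3.16 (1.87 to 1.90). In DOX4X 1, Mfap5 stood at 6.58 CPM (others 15.2 to 16.8), and in DOX4X 2, Vpreb3 stood at 28.9 CPM (others 8.84 to 11.2). In PBS 3, Gm21698 stood at 0.324 CPM (others 0.167 to 0.178) and P4ha3 at 49.7 (31.9 to 32.1), and in PBS 2, Pcna stood at 64.3 (53.3 to 55.0).

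The fall of 26 genes after 4 doses was given by 1 of 35 splits of the 8 libraries (the real one, 26 genes; highest other 3), which argues against chance only with DOX1X in the fit, because 3 of 35 splits gave at least the 1 gene found with the 8 libraries fitted alone (highest other 3), and the real split also parts the flow cells. The stromal identity list had a median of -0.063 (interquartile range 0.343) against -1.02 for the called genes. This met the bound set against a lower share of stromal cells as the whole cause, but it cannot decide the question. The called genes were chosen by their p in the same comparison, so they would lie below an unselected list in any case. Scaling can also hide a fall that most transcripts share. A smaller share of 1 kind of stromal cell was not tested. Flow cell as the whole cause stays open: with genes chosen on 2 PBS libraries and measured against the others, DOX1X 1 and 2 lay lower within flow cell 1 in all 6 ways (21 to 25 of 26 genes), but the highest median of -0.27 missed the bound of -0.3 set for it. With flow cell as a term all 26 genes stayed lower, with a median of -0.97 (median SE 0.29) against -1.02 (median SE 0.15) without it, and 0 passed with edgeR (24 at an unadjusted p under 0.05): the SE grew, and for Mmp9 (-1.92 to -1.16), P4ha3 (-1.03 to -0.68) and Serpine2 (-0.70 to -0.44) the fold was smaller, while the endothelial median went from 0.85 to 0.04. An effect of doxorubicin could account for the fall, but the flow cell term rests on the 3 DOX1X libraries, of which only DOX1X 3 was on flow cell 2 (for Ddr2, Gpr27, P4ha3 and Serpine2, at an unadjusted p of 0.05 or more within flow cell 1, it lay above each DOX4X library in 100% of genes).

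Cell-cycle medians were higher in both doxorubicin groups at the preset correlation (adjusted p of 0.58 and 0.66 with an estimated correlation, 0 members called), with DOX1X 3 (score 3.93) below PBS 1, 2 and 3 (4.33, 4.85 and 4.09), and RNA from other marrow cells may be the source. Over 11 libraries the group-centred scores had Pearson r = 0.717 (one-sided exact permutation p = 0.0269) and Spearman rho = 0.555 (p = 0.0709), which met the criterion written before the result was seen. Without DOX1X 3 and DOX4X 3, the farthest from the median of the group-centred blood-cell score, r was 0.488 (0.401 with groups centred again, exact permutation p = 0.191). Leaving out the farthest libraries narrows the range of the score and tends to lower r. This therefore cannot show whether the relation rests on those 2 libraries. Within flow cell 1, r was 0.205 (6 libraries, exact permutation p = 0.417), and flow cell 2 held 5, too few for r, where DOX4X 1 and 2 lay above DOX4X 3 and 4 on both scores. The marker covariate moved the cell-cycle median from 0.73 to -0.06 in DOX4X, where its camera direction stayed upward, and from 0.56 to -0.38 in DOX1X, while flow cell as a term moved it to 1.90 in DOX4X and 0.84 in DOX1X; more division of the sorted cells after doxorubicin was not tested and stays open.

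The title of PBS 4 begins with the doxorubicin abbreviation. On genes chosen with the other libraries (0 at the PBS mean, 1 at the DOX4X mean), PBS 4 lay at 0.553, above PBS 1 (0.427), PBS 2 (0.484) and PBS 3 (0.182). It lay below the DOX4X libraries (0.725 to 0.910), each held out against PBS 1, 2 and 3 and the other DOX4X libraries. The PBS mean used for PBS 1, 2 and 3 included PBS 4, so these positions were not had in the same way. A position toward DOX1X was not tested. It met neither bound, above 0.7 or below 0.5, so a wrong treatment label could not be excluded. Without PBS 4, 80 genes passed in place of 26. This count cannot decide the label, because it also moved without libraries whose labels agree (47 without DOX1X 3, 0 without DOX4X 3). On the first principal component, the axis of largest spread between libraries (21.9% of variance), PBS 4 lay at 56.7. DOX1X 3 lay at 43.5, DOX4X 3 at 30.03 and the others between -36.2 and 11.4. The libraries high on this axis thus came from each group and from both flow cells.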

How the results depend on the processing

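The flow cell settings, the fits within a flow cell and an estimated correlation together with a covariate were chosen only after the results were seen. In each of 24 alternatives, the genes called lower after 4 doses that could be tested were all lower, with medians from -1.14 to -0.88. These genes were chosen for their fall in the same libraries, so their direction was largely fixed in advance and is no separate support. The number of calls was less stable, and where no construction is named the cause was not tested. For DOX4X against PBS, the count of 26 became 590 with DESeq2, 56 with limma-voom, 1 with only the compared groups, 64 at an adjusted p under 0.10, 5 with the marker covariate, 6 with flow cell as a term (none shared with the 26) and 0 to 80 with a library left out. The 14 lists became 0 with an estimated correlation (alone, with the marker covariate or with flow cell as a term, as in the other comparisons) and 1 with fry, and 14 to 16 with a library left out. For DOX1X against PBS, 1 gene became 49 with DESeq2, 5 within flow cell 1 and 1 to 2 with a library left out, and 15 lists became 7 with the marker covariate, 0 with an estimated correlation, 0 with fry and 10 to 15 with a library left out. For DOX4X against DOX1X, 1 gene became 27 with DESeq2 and 1 to 2 with a library left out, and 9 lists became 14 with the marker covariate, 14 with flow cell as a term, 0 with an estimated correlation, 0 with fry and 9 to 14 with a library left out. The correlation of the comparisons with PBS was 0.54 to 0.66 with a library left out, and with split controls 0.22, 0.20, 0.19, 0.23, 0.21 and -0.011, where fewer controls enter each comparison.

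Fold changes of genes and test directions of lists turned as follows. The marker covariate was built from the neutrophil, monocyte and macrophage, B lineage and erythroid lists. Lower values of these lists and of Hba-a1 with it therefore follow from its construction. For the other turns the cause was not tested. In DOX4X against PBS with flow cell as a term, mt-Nd2 had -0.0086, Lepr 0.28, Cxcl12 0.12, Angpt1 0.21, Sp7 0.12, Col1a1 0.32, Bglap -0.40, Il6 -0.17 and the mitochondrial list -0.0086. With the marker covariate, Mdm2 had -0.011, Il6 -0.13, Mki67 -0.18 and the monocyte list -0.38, and with the stricter filter Cdkn1a had 0.012. With a library left out, the range was -0.0016 to 0.11 for Kitl, -0.067 to 0.082 for Csf1, -0.17 to 0.32 for Bglap, -0.14 to 0.21 for Cdkn1a, -0.017 to 0.065 for Mdm2 and -0.051 to 0.30 for Il6. In DOX1X against PBS with the marker covariate, Hba-a1 had -0.089, the erythroid list -0.089, DNA repair -0.16, cell cycle -0.38 and mural markers 0.094. Neutrophil markers had a median of 0.41 in place of 1.53, still above 0, with the direction of the test turned. With a library left out, Vwf ranged from -0.019 to 1.81 and Tubb1 from -0.20 to 2.34, both lowest without DOX1X 2. In DOX4X against DOX1X, neutrophil markers had 0.36 with flow cell as a term and 0.37 within flow cell 2, and megakaryocyte markers 0.18 within flow cell 2. Medians of the lists that follow changed sign while the direction of the test did not. With the marker covariate, DNA repair had -0.013 and cell cycle -0.063 in DOX4X against PBS. Antigen presentation in DOX1X against PBS had -0.019 without DOX1X 3, -0.019 with flow cell as a term and -0.021 within flow cell 1. Without DOX1X 2, megakaryocyte markers had -0.18 in DOX1X against PBS and 0.073 in DOX4X against DOX1X, where flow cell as a term gave 0.17. The settings named for antigen presentation all compare DOX1X 1 and 2 with the PBS libraries, so they are not separate results. There the flow cell cannot be told apart from DOX1X 3. Among single genes and lists, 3441 alternatives kept direction and side of the threshold, 530 lost the call, 51 gained it and 45 turned. Genes not called in the main test that stayed uncalled count among those kept. Of the 26 genes called after 4 doses, Timp1 lost the call least often (4 of 24 alternatives) and Skil most often (16 of 24). Of 54 genes named for DOX4X against PBS that had not passed, flow cell as a term made 16 larger and 7 smaller by over 1.5 times and turned 8.

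Replicate numbers did not pair the libraries: of 10 same-number pairs, 2 had a correlation over 0.1 (-0.119 to 0.347), and 2 of 11 libraries correlated best with their own number. With the replicate block, 10 genes passed for DOX4X against PBS, 6 for DOX1X against PBS and 2 for DOX4X against DOX1X, and DNA repair no longer passed in DOX1X against PBS (camera adjusted p = 0.12).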

Other observations

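The tests of other splits given in this section were planned, and the weighing of gene lists by change in either direction was chosen only after the results were seen. In DOX4X against PBS, the NRF2 antioxidant list (19 of 31 genes lower, median -0.05, camera adjusted p = 0.063, unadjusted 0.038) and the fibroblast and periosteal list (median -0.02, camera adjusted p = 0.39) did not pass the camera threshold, while fry for change in either direction gave adjusted p of 1.14e-04 and 0.0015. Both held members that lay higher and lower (2 rose and 2 fell when adjusted over the list alone for NRF2, 1 and 2 for the fibroblast list), and none passed over all genes. Srxn1 (sulfiredoxin) had a log2 fold change of -0.53 (SE 0.09, edgeR adjusted p = 0.060) and Gpx3 (a secreted glutathione peroxidase) -0.63 (SE 0.13, 0.092), while Gpx1 (a glutathione peroxidase) had 0.46 (SE 0.11, 0.12) and Txn1 (thioredoxin) 0.24 (SE 0.07, 0.19). Fap (fibroblast activation protein) had -0.48 (SE 0.08, edgeR adjusted p = 0.060) and Postn (periostin) -1.15 (SE 0.28, 0.13), while Mfap5 (a microfibril protein) had 1.20 (SE 0.31, 0.14) and Dpp4 (a surface peptidase) 0.87 (SE 0.29, 0.23). The same test passed for 12 of 30 lists, with adjusted p of 2.52e-06 for senescence, 2.21e-04 for osteoclast, 0.0013 for osteoblast and 0.0022 for matrix genes. It asks only whether members change, and over all 17838 genes 2471 had an unadjusted edgeR p under 0.05 (891.9 expected by chance). It was not run with flow cell as a term or on other splits. With flow cell as a term Txn1 had 0.015 and Gpx1 0.70, and with the marker covariate Dpp4 had 0.36.

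Other splits of the same libraries gave results as large in most cases. For DOX1X against PBS, 7 of 35 splits gave at least 1 gene (highest other 11), and for DOX4X against DOX1X 3 of 35 did (highest other 3), so chance could not be excluded for these counts. For the gene lists, 13 of 35 splits gave at least the 14 of DOX4X against PBS (highest other 16), 5 of 35 at least the 15 of DOX1X against PBS (highest other 16) and 31 of 35 at least the 9 of DOX4X against DOX1X (highest other 19), so chance could not be excluded for any of the list counts. The split of PBS 1, 2 and 3 from the rest, which gave 11 genes, sets PBS 4 with the DOX1X libraries.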
